A study of Homo sapiens with 14 samples.

How the data were processed

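Polyadenylated RNA from 14 samples of the embryonic stem cell lines UCLA1 and UCLA4 was sequenced as stranded RNA-seq, per the labels. Reads had been aligned to hg19 with TopHat2 2.1.0 and counted per gene with HTSeq 0.6.1p1, per the submitters' processing notes; the strand setting of the counting is not stated. The deposited values are raw counts per gene, 1 table per sample, with no scaling. They came in 2 formats: 8 tables (clones 9 and 12, clone 4 labelled XIST-negative, primed cells) listed 25369 genes and no reads under the summary line for reads that align more than once, and 6 tables (late clone 4, the reprimed sample, UCLA4) listed 26364 genes and such reads. Summary lines held 12.4 to 21.4% of all counts in the first format and 28.2 to 34.4% in the second and were left out of library sizes and tests. In the first format 28 gene names read as dates, the mark of a spreadsheet, and were left out with all other names not listed in both formats. The 24790 genes listed in every table were kept, which left out 0.56 to 0.87% of gene counts. No group has libraries in both formats, so that late against earlier clone 4, the reprimed sample against UCLA1 cells and UCLA1 against UCLA4 are also comparisons of formats.

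Chromosomes were assigned by name from GENCODE v29 (22620 genes), else by synonym (711) or symbol (600) in a RefSeq table; 834 genes had no match and 25 lay on more than 1 chromosome, and 1002 of the shared genes were X-linked. Transcript length and GC content came from reference transcript sequences, with the longest transcript taken per gene name. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes with at least 0.5 CPM (counts scaled to library size) in at least 2 libraries were kept (16548), scaled by TMM and fitted with 1 quasi-likelihood model over 8 groups and 14 libraries (6 residual degrees of freedom, median prior degrees of freedom 3.42, common dispersion 0.136). Replicates are taken as independently processed samples of 1 culture condition, so that p-values measure the spread between samples, which may be technical. Contrasts were tested two-sided, with Benjamini-Hochberg adjustment within each contrast and calls at an adjusted p under 0.05. The contrasts were naive against primed UCLA1 (mean of clones 9, 12 and 4), XIST-positive against XIST-negative by label in UCLA1 (clones 9 and 12 against clone 4) and in UCLA4, the difference between these, late against earlier clone 4, reprimed against primed, reprimed against naive, and clone 12 against clone 9. Fitted folds average groups on the log scale and can differ from a ratio of mean CPM. Late clone 4 and the reprimed sample are single libraries, tested with the spread of the groups that have pairs.

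Named genes followed a rule fixed before the data were examined, as were groups, contrasts, lists and most alternatives. XIST, XACT, TSIX and JPX came first. Then, per contrast, came the 8 largest rises and the 8 largest falls among called genes with a mean log2 CPM of at least 2 and all libraries of one side above the other, 6 X-linked genes each way by the same rule, and up to 4 called members of each list by smallest adjusted p. A gene with 0 counts on one side is given as at least so many fold, against a floor of 3 counts over the group, and a gene with 1 to 3 counts as a ratio of pooled counts with a 95% interval that covers counting error alone. The 20 lists (384 genes) held X-inactivation RNAs and regulators, genes known to escape X inactivation, genes known to be subject to it, naive, primed and shared pluripotency, trophoblast, hypoblast and endoderm, mesoderm and primitive streak, neural ectoderm, fibroblasts and feeder cells, DNA methylation, imprinted genes, germline genes, preimplantation genome activation, MEK and ERK targets, WNT targets, glycolysis, the respiratory chain, and stress and dissociation. Lists and chromosomes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The second form also uses the 6 residual degrees of freedom, so its p-values can rise where the correlation is lower. For X-linked genes the estimated correlation was 0.00675. List members were also adjusted over the list alone.

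The X shift is the median log2 fold change of X-linked genes minus that of autosomal genes, tested with camera. The relative X level of a library used log2 CPM with a pseudocount of 1, and its group differences were tested by exact permutation of libraries. Escape and subject genes were compared by permuting gene labels (100000 draws), and genes are not independent replicates.

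Alternatives were the size factors of DESeq2 (median of ratios), the Wald test of DESeq2 1.42.0, no filter on low counts, a filter at 2 CPM, the compared groups alone, a replicate block, each replicate left out, a fold threshold, means for medians, autosomal scaling factors, X-linked genes without escape genes, a pseudocount of 0.25, the percent of counts on X and late clone 4 among naive cells. Replicate numbers tied the samples of 3 groups and not of the others: deviations of replicate 1 from replicate 2 correlated at 0.768 between clones 12 and 9, 0.532 between clone 12 and primed cells and 0.477 between clone 9 and primed cells, and from -0.101 to 0.238 for other pairs of groups. The second libraries of clones 9, 12 and primed cells therefore formed a class of their own, and a term for that class was added after the data were seen. The UCLA4 libraries labelled XIST-negative differed least of all pairs (chi-square per gene 2.735, against 79.85 to 295.3), though beyond sampling noise, and were counted as 2. Whether they are separate cultures is not stated, and they may come from 1.

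The code was tested on simulated counts with 100 genes changed per fold. These 200 changed genes were far fewer than the 6278 called for naive against primed, so the adjusted threshold was stricter than in that contrast. The recovery below is therefore no measure of power in real contrasts with many calls. Calls recovered 2% of 2-fold and 55% of 4-fold changes for naive against primed, 6% and 53% for the UCLA1 label contrast, 0% and 26% for UCLA4, 0% and 1% for late against earlier clone 4 and for reprimed against primed, 0% and 19% for reprimed against naive, 0% and 29% for clone 12 against clone 9, and 0% and 0% for the difference between lines. None had the wrong direction, and 0 to 5 unchanged genes were called. A simulated X shift of -0.6 was recovered as -0.62, and one of 0 as -0.0047. Gene counts were 19022177 to 48339000 per library, and genes below the filter were not tested. Y-linked genes are not reported, and 2 genes that the naming rule picks are not reported here.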

Results

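RNA-seq gene counts were obtained from 14 samples of 2 human embryonic stem cell lines, UCLA1 and UCLA4. UCLA1 gave 10 samples: 2 primed samples, 2 samples each of naive clone 9 and naive clone 12 (both labelled XIST-positive), 2 samples of naive clone 4 labelled XIST-negative, 1 late-passage sample of clone 4 labelled XIST-positive and 1 reprimed sample. UCLA4 gave 4 naive samples, 2 labelled XIST-negative and 2 labelled XIST-positive. Naive cells had been kept in 5iLAF, a medium that holds human pluripotent cells close to the state of the preimplantation embryo, whereas primed cells represent the conventional, later state. Counts assigned to genes came to 19022177 and 48339000 in the samples of clone 9, 28309729 and 36416950 in clone 12, 29198117 and 37934732 in clone 4 labelled XIST-negative and 32097616 in late clone 4. They were 23564527 and 29996017 in primed cells and 28272671 in the reprimed sample. UCLA4 had 29261630 and 28233900 in the samples labelled XIST-negative and 33771802 and 28071229 in those labelled XIST-positive. Of the 24790 genes listed for every library, 16548 passed the expression filter, 609 of them X-linked and 15657 autosomal. The groups allow XIST, the long noncoding RNA that coats and silences an X chromosome, and the transcript level of the X chromosome to be compared between states, clones and lines.

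XIST was close to the floor in primed cells and present in every naive library, and the labels mostly followed its level. It reached 775 and 365 CPM (counts scaled to library size) in the libraries of clone 12, 706 and 99.2 CPM in those of clone 9 and 825 CPM in late clone 4. The libraries labelled XIST-negative were not empty of it: clone 4 held 37.8 and 105 CPM and UCLA4 held 23.9 CPM in both, against 281 and 182 CPM in UCLA4 labelled XIST-positive. The second library labelled clone 9 XIST-positive thus lay below the second library labelled clone 4 XIST-negative, so groups are named by their labels throughout. Primed cells held 1.19 and 0.567 CPM and the reprimed sample 0.48 CPM. Across the clone groups XIST was 348 ± 325 CPM (SD, n = 6) in naive UCLA1 cells against 0.876 ± 0.437 CPM (SD, n = 2) in primed cells, a log2 fold change of 8.18 ± 1.08 (SE; edgeR adjusted p = 0.000426). Between the UCLA1 clones labelled XIST-positive and clone 4 labelled XIST-negative the change was 2.74 ± 0.79 (adjusted p = 0.0459), with 3 of the 4 positive libraries above both negative ones. In UCLA4 it was 3.28 ± 0.87 (adjusted p = 0.364) and in late against earlier clone 4 it was 3.53 ± 0.95 (adjusted p = 0.0517), neither past the threshold. JPX, a noncoding neighbour of XIST, gave -0.59 ± 0.33 between naive and primed cells (adjusted p = 0.193). TSIX, which runs antisense to XIST, gave 1.39 ± 0.41 (adjusted p = 0.0241), a value that is uncertain because reads from overlapping antisense genes may not be separable in these counts. XACT, another X-linked noncoding RNA, was listed for 6 libraries and held 8 counts in late clone 4, 3 in the reprimed sample, 8 and 7 in UCLA4 labelled XIST-negative and 3 and 5 in UCLA4 labelled XIST-positive.

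**Figure D1:**
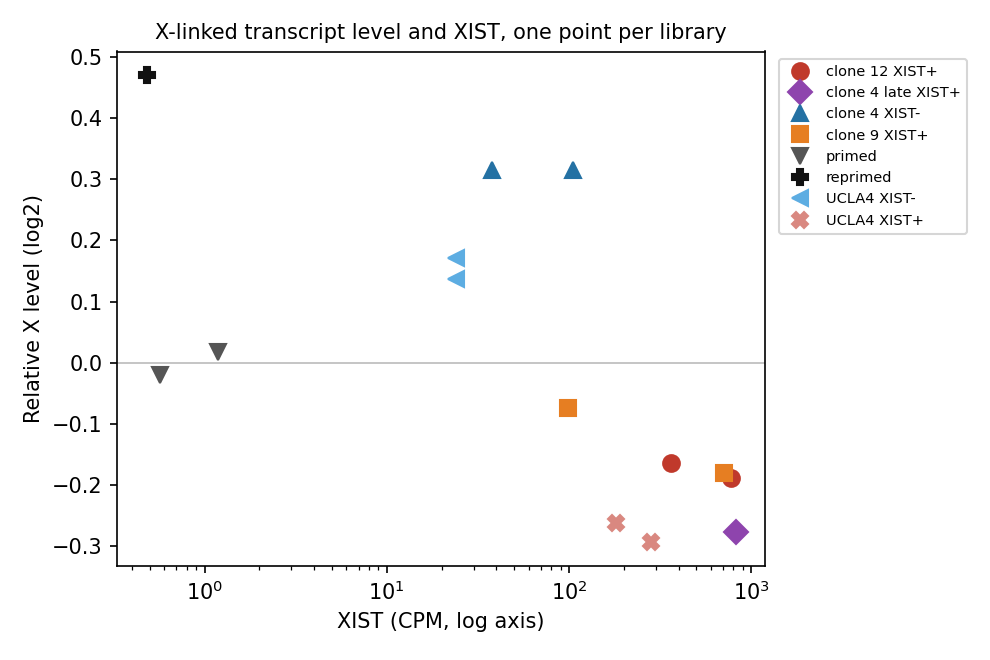
Relative X level (log2, vertical axis) against XIST (CPM, log axis), one point per library, with colour and shape giving the group. The 7 libraries labelled XIST-positive lie between -0.294 and -0.0739 on the vertical axis, the 4 naive libraries labelled XIST-negative between 0.136 and 0.314, and the reprimed sample at 0.47.

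The transcript level of X-linked genes differed with the XIST label, and no difference between naive and primed cells as a whole was detected. The relative X level, which is the median over X-linked genes of the deviation from each gene's mean minus the same median over autosomal genes, on a log2 scale, was lower in all 7 naive libraries labelled XIST-positive than in all 4 labelled XIST-negative. It was -0.18 ± 0.018 in clone 12, -0.13 ± 0.075 in clone 9, -0.28 ± 0.022 in UCLA4 labelled XIST-positive, 0.31 ± 0.00022 in clone 4 labelled XIST-negative and 0.15 ± 0.025 in UCLA4 labelled XIST-negative (SD, n = 2 each). Primed cells held -0.0014 ± 0.027 (SD, n = 2), late clone 4 held -0.28 and the reprimed sample held 0.47. The share of gene counts on X-linked genes ranged from 3.0% in UCLA4 labelled XIST-positive to 5.04% in the reprimed sample, with 3.69% in primed cells. Permuting the XIST label within lines gave a mean difference of -0.46 with an exact two-sided p = 0.00794, the smallest that the arrangements can give. Single libraries were permuted, several of them from the same clone, and clones are not independent samples of an XIST state. The p-value is therefore no measure of an effect of the label across clones. The size of this difference depended on the filter and the pseudocount: with the same exact p it was -0.17 with no filter on low counts, -0.60 with a filter at 2 CPM and -0.61 with a pseudocount of 0.25. Within UCLA1, clones 9 and 12 differed from clone 4 by -0.47 (exact permutation p = 0.0667, the smallest of 15 splits), and within UCLA4 the difference was -0.43 (exact permutation p = 0.333, the smallest of 6 splits). Between naive and primed UCLA1 cells the difference was 0.005 (exact permutation p = 1, 28 splits). Clones 9 and 12 lay at -0.15 from primed cells (exact permutation p = 0.0667, 15 splits) and clone 4 at 0.32 (exact permutation p = 0.333, 6 splits). The second libraries of clone 9, clone 12 and primed cells deviated together from the first. Clones 9 and 12 lay at -0.20 from primed cells among first libraries (exact permutation p = 0.333, 3 splits) and at -0.098 among second libraries (exact permutation p = 0.667, 3 splits).

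Naive and primed UCLA1 cells were set against each other to describe the 2 states. All naive pluripotency genes measured were higher in naive cells and most primed ones lower, and the genes called higher included members of the trophoblast, germline and preimplantation lists. Among genes with a mean log2 CPM of at least 2, the largest fitted rises included those of CNR2, a cannabinoid receptor, at least 464-fold higher; of MYO1G, a myosin of blood cells, at least 221-fold; and of CEACAM6, an adhesion molecule, at least 181-fold, each against 0 counts in primed cells. The calcium-binding S100P followed with a single count in primed cells (ratio 1560, 95% counting interval 280 to 61700). CGA, the alpha subunit of glycoprotein hormones, rose by 10.36 ± 2.18 on the log2 scale (adjusted p = 0.00508; 151 ± 144 against 0.091 ± 0.028 CPM; SD, n = 6 and 2). KHDC1L rose by 9.80 ± 0.63 (adjusted p = 8.84e-06) and TRIM60 by 9.63 ± 0.33 (adjusted p = 1.1e-06). By the same filter, the largest falls were those of the deubiquitinase USP44 (-6.81 ± 0.35, adjusted p = 3.45e-06), VRTN (-6.24 ± 0.27, adjusted p = 1.75e-06), LRRN1 (-5.90) and SMPDL3B (-5.58). The secretory granule protein SCG3 (-5.34), the surface glycoprotein CD24 (-5.31 ± 0.21, adjusted p = 1.31e-06; 95.8 ± 89.2 against 2726 ± 323 CPM), the melanosome protein PMEL (-5.08) and the zinc-finger factor SALL2 (-4.89) also fell. All 6 naive libraries lay on one side of both primed libraries for each of these genes.

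In all, 6278 of 16548 genes differed between naive and primed cells (edgeR quasi-likelihood test, adjusted p under 0.05), 3014 higher and 3264 lower in naive cells; 6342 did when clone 4 was left out of the naive mean. All 25 naive pluripotency genes rose (25 adjusted over the list alone; camera adjusted p = 2.51e-20, adjusted p = 0.0527 with an estimated correlation). Among them were DNMT3L, a cofactor of de novo DNA methylation (9.54 ± 0.31, adjusted p = 1.1e-06; 1216 ± 344 against 1.57 ± 0.079 CPM), the maternal-effect gene KHDC3L (8.38 ± 0.45) and the transcription factor KLF5 (5.22 ± 0.28). Of 21 primed pluripotency genes, 19 fell (20 adjusted over the list alone; camera adjusted p = 1.79e-13, adjusted p = 0.0527 with an estimated correlation), led by the receptor phosphatase PTPRZ1 (-8.72 ± 0.34, adjusted p = 1.31e-06). The 13 shared pluripotency genes went both ways, 3 up and 4 down (3 and 5 adjusted over the list alone; camera adjusted p = 0.543). GDF3 rose by 3.57 ± 0.51, and SOX2 (-1.83 ± 0.24) and LIN28A (-1.49 ± 0.21) fell. Of 13 trophoblast genes 9 rose (9 adjusted over the list alone; camera adjusted p = 0.000713, adjusted p = 0.479 with an estimated correlation). GCM1 (8.27 ± 1.41) and HAND1 (5.13 ± 0.58) were among them, and CDX2 had 1 count in primed cells (ratio 243, 95% counting interval 43.5 to 9610). Of 10 genes of preimplantation genome activation 9 rose (9 adjusted over the list alone; camera adjusted p = 5.72e-06, adjusted p = 0.35 with an estimated correlation), with ZSCAN4 at least 70.4-fold and MBD3L2 at least 48.4-fold higher against 0 counts. TRIM43 had 1 count in primed cells (ratio 423, 95% counting interval 75.8 to 16700). Of 15 germline genes 9 rose and 3 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.0509), including the synaptonemal complex protein SYCP3 (8.65 ± 0.66) and RNF17 (8.06 ± 0.69), while TEX15 fell (-4.12 ± 0.46). Imprinted genes rose in 10 of 24 cases and fell in 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00344, adjusted p = 0.302 with an estimated correlation). NLRP2 rose by 4.85 ± 0.26, and the paternally expressed PEG3 had 1 count in primed cells (ratio 1540, 95% counting interval 276 to 60800).

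Targets of MEK and ERK signalling were lower in naive cells: 13 of 18 fell and none rose (1 up and 13 down adjusted over the list alone; camera adjusted p = 5.72e-06, adjusted p = 0.302 with an estimated correlation). The phosphatase DUSP6 (-5.09 ± 0.47), the ETS factors ETV1 (-4.55 ± 0.29) and ETV5 (-3.40 ± 0.35) and the inhibitor SPRY1 (-3.03 ± 0.26) all fell. Of 9 neural genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.0131, adjusted p = 0.227 with an estimated correlation), including MAP2 (-5.24 ± 0.46). Of 17 stress response genes 10 rose and 3 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.00742, adjusted p = 0.479 with an estimated correlation). The kinase-like TRIB3 (4.14 ± 0.39), DDIT3 (2.84 ± 0.50) and MDM2 (2.42 ± 0.34) rose and EGR1 fell (-4.05 ± 0.67). The DNA methylation machinery went both ways, 3 up and 2 down of 9 (3 and 2 adjusted over the list alone; camera adjusted p = 0.543). The demethylases TET2 (4.03 ± 0.49) and TET1 (1.49 ± 0.37) rose and the methyltransferase DNMT3B fell (-2.70 ± 0.23, adjusted p = 4.23e-05). The remaining lists did not pass the set test except 1. Hypoblast and endoderm genes numbered 5 up and 4 down of 12 (5 and 4 adjusted over the list alone; camera adjusted p = 0.639). Mesoderm genes numbered 3 down of 7 (3 adjusted over the list alone; camera adjusted p = 0.13) and WNT targets 2 up and 1 down of 11 (2 and 1 adjusted over the list alone; camera adjusted p = 0.248). Glycolysis genes numbered 3 up and 6 down of 19 (3 and 6 adjusted over the list alone; camera adjusted p = 0.543), with PFKL up (1.66 ± 0.22) and PFKM down (-1.91 ± 0.21). Respiratory chain genes numbered 2 up and 1 down of 40 (1 and 0 adjusted over the list alone; camera adjusted p = 0.543). Fibroblast genes numbered 3 up and 1 down of 12 (3 and 1 adjusted over the list alone; camera adjusted p = 0.511). The collagen gene COL3A1, one of the 3, rose by 6.73 ± 1.79 (adjusted p = 0.0153). Its level was 14360 and 5195 CPM in the libraries of clone 4 labelled XIST-negative and 18.6 to 882 CPM in those of clones 9 and 12.

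X-linked genes changed in both directions between naive and primed cells, 134 up and 152 down of 609. MAGEB2, a gene otherwise active in testis, had 2 counts in primed cells (ratio 866, 95% counting interval 240 to 7150), and LUZP4 (8.33 ± 1.03), LOC100506790 (7.76 ± 1.03) and SLITRK2 (6.94 ± 0.85) rose with it. TKTL1, a transketolase-like gene, had 3 counts in primed cells (ratio 133, 95% counting interval 45.5 to 648). NAP1L3 (-4.83 ± 0.26), AP1S2 (-4.65 ± 0.21), TMEM47 (-4.55 ± 0.20), BEX1 (-4.54 ± 0.51), the neuroligin NLGN4X (-4.18 ± 0.17; 17.1 ± 8.7 against 268 ± 47.9 CPM) and PDZD4 (-3.83 ± 0.43) fell, BEX1 with the highest adjusted p of these (0.000175). The median log2 fold change of X-linked genes minus that of autosomal genes, the X shift, was -0.048 (limma camera p = 0.52, p = 0.478 with an estimated correlation). It was 0.10 with no filter on low counts and 0.19 among genes with a mean log2 CPM of at least 4. Against primed cells, clones 9 and 12 alone gave an X shift of -0.29 (camera p = 0.0576, p = 0.0669 with an estimated correlation), which was 0.0083 among genes with a mean log2 CPM of at least 4. Clone 4 labelled XIST-negative gave 0.38 (camera p = 0.0505, p = 0.061 with an estimated correlation), a shift that passed with the replicate block (0.39, camera p = 0.0492) and with a term for the second libraries of clones 9 and 12 and primed cells (0.46, camera p = 0.00672), and did not without the first primed library (0.32, camera p = 0.132). Among X-inactivation RNAs and regulators 4 of 18 rose (4 adjusted over the list alone; camera adjusted p = 0.543), including XIST and the ubiquitin ligase RLIM (1.32 ± 0.21, adjusted p = 0.00124). Of 28 genes known to escape X inactivation 2 rose and 4 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.866), USP9X (-1.88 ± 0.19) and MED14 (-1.65 ± 0.20) among them. Of 55 genes known to be subject to it 17 rose and 3 fell (17 and 3 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.302 with an estimated correlation). BTK (5.10 ± 0.52) and LAMP2 (1.69 ± 0.20) were among the rises.

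The UCLA1 naive clones labelled XIST-positive (clones 9 and 12) were compared with clone 4 labelled XIST-negative to ask what goes with XIST in the naive state. Genes called higher in clones 9 and 12 included members of the germline and naive lists. Genes called lower included WNT targets, X-linked genes, COL4A1, COL4A2, COL18A1 and FLT1. The germline gene RNF17 rose by 4.66 ± 0.52 on the log2 scale in clones 9 and 12 (adjusted p = 0.000622; 62.0 ± 17.9 against 2.37 ± 1.14 CPM; SD, n = 4 and 2). PAX8-AS1 rose by 4.39 ± 0.43 (adjusted p = 0.000355) and PEG3 by 4.06 ± 0.41 (adjusted p = 0.000423; 43.0 ± 6.26 against 2.57 ± 1.06 CPM). The cytochrome CYP2E1 (3.53 ± 0.49), LINC01108 (3.06 ± 0.75), FAM111B (3.05 ± 0.73) and the meiotic RNF212 (2.87 ± 0.46) also rose. LMCD1 (-7.12 ± 0.58), the VEGF receptor FLT1 (-6.82 ± 0.38, adjusted p = 2.65e-05), NPNT (-6.79 ± 0.44), COL18A1 (-6.68 ± 0.56) and the cardiac actin ACTC1 (-6.66 ± 0.71) fell. The basement membrane genes COL4A2 (-6.31 ± 0.58), HSPG2 (-6.26 ± 1.10) and COL4A1 (-6.15 ± 0.50, adjusted p = 0.000159; 26.0 ± 12.1 against 1800 ± 556 CPM) fell as well. For each of these genes all 4 libraries of clones 9 and 12 lay on one side of both clone 4 libraries.

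**Figure D2:**
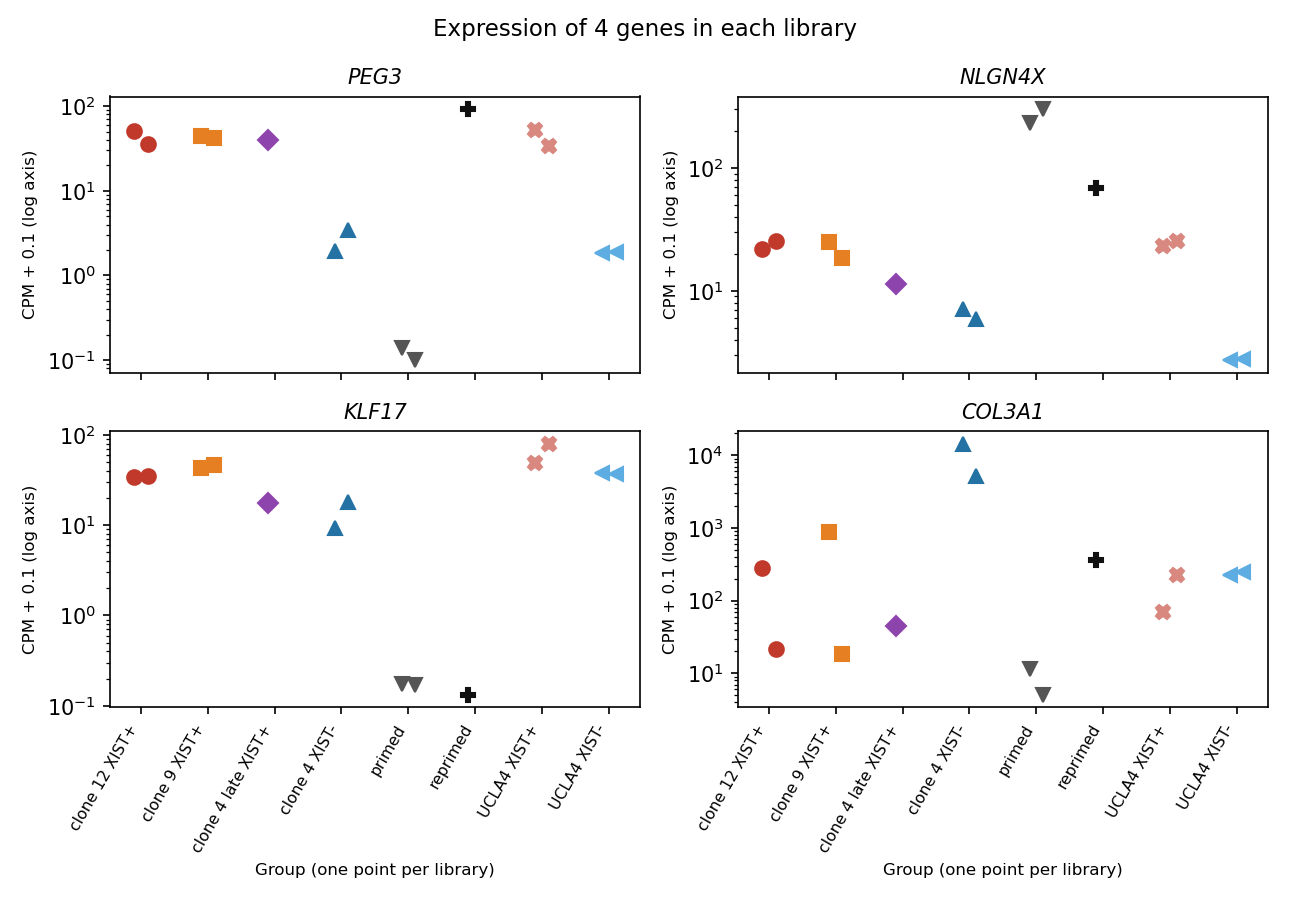
CPM plus 0.1 (log axis) of PEG3, NLGN4X, KLF17 and COL3A1, one point per library, by group. PEG3 lies between 1.76 and 3.32 CPM in the 4 naive libraries labelled XIST-negative and between 33.9 and 52.5 CPM in the 7 labelled XIST-positive, and COL3A1 reaches 14360 CPM in clone 4.

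Altogether 2566 genes passed the test, 716 higher and 1850 lower in clones 9 and 12. Of 25 naive pluripotency genes 8 rose (8 adjusted over the list alone; camera adjusted p = 4.14e-05, adjusted p = 0.407 with an estimated correlation). They included KLF17 (1.53 ± 0.31, adjusted p = 0.0113; 40.0 ± 5.99 against 13.7 ± 6.28 CPM), DPPA3 (2.16 ± 0.52) and DPPA2 (1.39 ± 0.30). Of 15 germline genes 7 rose (8 adjusted over the list alone; camera adjusted p = 2.28e-05, adjusted p = 0.407 with an estimated correlation), with TDRD12 (4.24 ± 0.73), GTSF1 (2.49 ± 0.50) and SYCP3 (2.25 ± 0.44) beside RNF17. Of 21 primed genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; camera adjusted p = 0.0246, adjusted p = 0.461 with an estimated correlation). HMGA2 (-2.52 ± 0.20) and CD24 (-2.40 ± 0.23) fell and OTX2 rose (1.63 ± 0.25). Of 12 fibroblast genes 7 fell in clones 9 and 12 (8 adjusted over the list alone; camera adjusted p = 0.000311, adjusted p = 0.461 with an estimated correlation). LUM changed by -9.87 ± 0.61 (adjusted p = 4.24e-05; 0.635 ± 0.233 against 574 ± 529 CPM) and COL3A1 by -5.24 ± 1.28 (adjusted p = 0.0242). Of 11 WNT targets 7 fell (7 adjusted over the list alone; camera adjusted p = 4.14e-05, adjusted p = 0.407 with an estimated correlation). LEF1 (-6.34 ± 0.58), SP5 (-4.94 ± 0.49) and BMP4 (-2.94 ± 0.26) were among these. Of 12 hypoblast and endoderm genes 5 fell (5 adjusted over the list alone; camera adjusted p = 0.00623, adjusted p = 0.461 with an estimated correlation), with GATA4 at -3.99 ± 0.46. Trophoblast genes fell in 3 of 13 cases (4 adjusted over the list alone; camera adjusted p = 0.027, adjusted p = 0.497 with an estimated correlation), with HAND1 at -4.49 ± 0.42 and 117 ± 14.9 CPM in clone 4. The mesodermal receptor KDR was 1.58 ± 0.969 against 74.9 ± 32.5 CPM (-5.76 ± 0.36). Imprinted genes went both ways, 3 up and 5 down of 24 (3 and 6 adjusted over the list alone; camera adjusted p = 0.791). MEG8 rose by 3.07 ± 0.56, and H19 (-3.81 ± 0.71) and SNRPN (-3.31 ± 0.44) fell. Shared pluripotency genes numbered 1 up of 13 (3 adjusted over the list alone; camera adjusted p = 0.00519, adjusted p = 0.461 with an estimated correlation) and genes of preimplantation genome activation 2 up of 10 (3 adjusted over the list alone; camera adjusted p = 0.00106, adjusted p = 0.461 with an estimated correlation). Respiratory chain genes numbered 2 up of 40 (0 adjusted over the list alone; camera adjusted p = 2.28e-05, adjusted p = 0.476 with an estimated correlation). Their level was 0.67 and 0.77 in the second libraries of clones 12 and 9, against -0.14 and -0.15 in the first and -0.39 and -0.29 in clone 4. The fibroblast list as a whole was 2.66-fold higher in the first than in the second clone 4 library, 10.1-fold higher in the first than in the second library of clone 9 and 5.13-fold in clone 12.

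X-linked genes were lower in clones 9 and 12 as a class. Of 609 tested, 166 fell (27.3%, against 10.6% of autosomal genes) and 11 rose. The X shift was -0.62, which is 65.2% of the level relative to autosomal genes, and 74.5% of X-linked genes lay below the autosomal median (camera p = 1.06e-09, p = 0.000369 with an estimated correlation). The heparan sulfate sulfotransferase HS6ST2 (-4.77 ± 0.44), WWC3 (-4.71 ± 0.81), ELF4 (-3.72 ± 0.59), the interleukin receptor IL13RA1 (-3.69 ± 0.35), SLITRK2 (-3.66 ± 0.51) and the lysosomal sulfatase IDS (-3.48 ± 0.38) fell. Some X-linked genes went the other way. TEX11, a meiotic gene (3.39 ± 0.44, adjusted p = 0.0014), NLGN4X (1.82 ± 0.22, adjusted p = 0.000979; 22.5 ± 3.17 against 6.35 ± 0.852 CPM) rose, as did GK (1.25 ± 0.22), FAM58A (1.13 ± 0.30), DKC1 (1.07 ± 0.19) and IDH3G (0.90 ± 0.19). RLIM, an activator of XIST, fell (-0.71 ± 0.20, adjusted p = 0.0422). Of 28 escape genes 4 fell (4 adjusted over the list alone; camera adjusted p = 0.155). Subject genes numbered 7 down and 2 up of 55 (7 and 2 adjusted over the list alone; camera adjusted p = 0.158). Their level was 0.12 and 0.16 in the second libraries of clones 12 and 9. It was -0.067 and -0.16 in the first libraries and 0.14 and 0.19 in clone 4 labelled XIST-negative. The mean of escape genes minus that of subject genes was 0.017 (permutation p = 0.92 across genes, which are not independent replicates; Benjamini-Hochberg p = 0.92 over 8 contrasts). Clone and XIST label are the same split here, so that the comparison is one of clones. The count of 2566 was 662 and 1498 without the first and the second clone 4 library, 1642 without the second clone 12 library and 1186 from the compared groups alone. It was 4556 with a term for the second libraries of clones 9 and 12 and primed cells, where 45.0% of calls were higher against 27.9%, and DESeq2 gave 40.3%. The share was 6.8% and 11.9% without the first and the second clone 4 library and 8.85% from the compared groups alone.

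**Figure D3:**
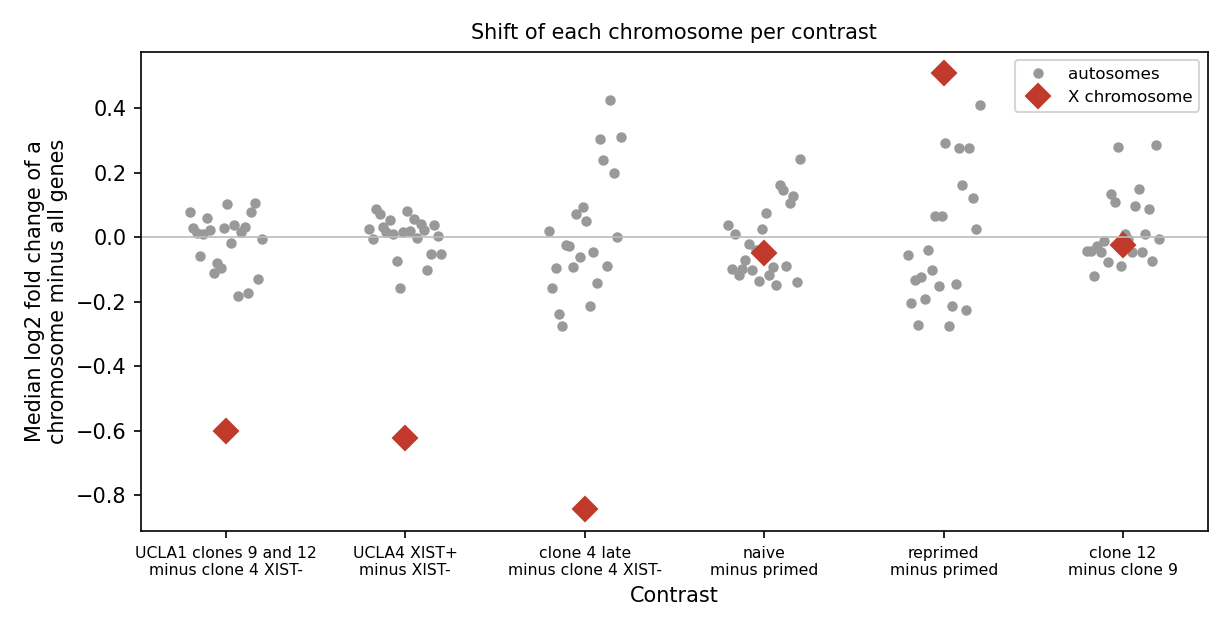
Median log2 fold change of each chromosome minus that of all genes in 6 contrasts, with autosomes as grey points and the X chromosome as a red diamond. The X chromosome lies at -0.60, -0.62 and -0.84 in the XIST contrasts of UCLA1, UCLA4 and late clone 4 and at 0.51 in reprimed against primed cells. In reprimed against primed cells autosomes run from -0.28 to 0.41.

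X-linked genes as a class were lower by a like amount in the same label contrast of UCLA4, with few single genes past the test. As a list, genes known to be subject to X inactivation had a lower median there than in UCLA1. A test of that difference passed at the preset correlation (camera adjusted p = 0.0177) and not with an estimated one (adjusted p = 0.398). The X shift was -0.64, or 64.4% of the level relative to autosomal genes, and 85.9% of X-linked genes lay below the autosomal median (camera p = 6.93e-27, p = 1.49e-05 with an estimated correlation). Of 4 genes that passed, all of them higher in the libraries labelled XIST-positive, NLGN4X rose by 3.19 ± 0.26 (adjusted p = 0.00691; 24.2 ± 1.36 against 2.65 ± 0.036 CPM; SD, n = 2 each). PEG3 rose by 4.60 ± 0.45 (adjusted p = 0.0158; 43.2 ± 13.1 against 1.77 ± 0.015 CPM). The other calls, LOC441601 (5.72 ± 0.60, adjusted p = 0.0222) and ZNF571-AS1 (4.33 ± 0.50, adjusted p = 0.0348), lie outside the rule for named genes and were named after their values were seen. Both libraries of one side lay above both of the other for all 4. In UCLA1 the same 4 genes were higher in clones 9 and 12 than in clone 4 in every library. Trophoblast genes were higher as a list (median 1.62, 0 of 13 called, camera adjusted p = 0.0239, adjusted p = 0.593 with an estimated correlation). They stood out in 1 library without a call. CGA held 980 and 6.37 CPM in the libraries labelled XIST-positive and 39.8 and 54.5 CPM in the others (3.39 ± 1.48, adjusted p = 0.726). GATA2 did not pass either (2.40 ± 1.30, adjusted p = 0.824). Genes subject to X inactivation were lower as a list with 0 of 55 called (0 adjusted over the list alone; camera adjusted p = 9.63e-12, adjusted p = 0.0338 with an estimated correlation; median -0.63). Of these, 51 lay below the autosomal median, and in UCLA1 the median of the same list was -0.19. Escape genes were less far down, 22 of 28 below it (camera adjusted p = 0.0192, adjusted p = 0.208 with an estimated correlation; median -0.29). The mean of escape genes exceeded that of subject genes by 0.35 (permutation p = 0.00018 across genes, which are not independent replicates; Benjamini-Hochberg p = 0.0014 over 8 contrasts). Genes of preimplantation genome activation were lower (median -1.98; 0 called, 4 down adjusted over the list alone; camera adjusted p = 1.53e-08, adjusted p = 0.409 with an estimated correlation). Stress (camera adjusted p = 0.00273) and germline lists (0.02) were also lower, germline genes opposite to UCLA1. Mesoderm (0.0239), naive (0.0314), shared pluripotency (0.0371) and DNA methylation lists (0.0455) were higher. All of these calls were lost with an estimated correlation. An unadjusted p under 0.05 was found for 1127 genes. The 4 calls became 0 without either library labelled XIST-negative or with these summed into 1 library, and 1 without the first library labelled XIST-positive. There were 8 calls with no filter on low counts, 141 from the compared groups alone, 112 with the term for second libraries and 162 by DESeq2. Most of these were lower in the libraries labelled XIST-positive: 24.8%, 15.2% and 24.1% were higher in the last 3.

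Chromosome by chromosome, X stood apart from the autosomes in both lines. In UCLA1 its median lay at -0.60 (adjusted p = 2.49e-08, adjusted p = 0.00851 with an estimated correlation; limma camera) while autosomes ran from -0.18 for chromosome 15 to 0.11 for chromosome 20. In UCLA4 it lay at -0.62 (adjusted p = 1.47e-25, adjusted p = 0.000342 with an estimated correlation) and autosomes from -0.16 for chromosome 10 (adjusted p = 0.0247, adjusted p = 0.0939 with an estimated correlation) to 0.086 for chromosome 3 (adjusted p = 0.144, adjusted p = 0.0469 with an estimated correlation). Of the 609 X-linked genes 393 (64.5%) had a negative log2 fold change in both lines, little more than the 62.3% that 72.6% in UCLA1 and 85.9% in UCLA4 give if the lines are unrelated. Of autosomal genes 25.2% did, against 23.7% if unrelated. The log2 fold changes of the 2 lines correlated at 0.16 among X-linked and 0.158 among autosomal genes (Pearson), or 0.276 and 0.0894 by rank (Spearman).

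The XIST contrast differed between the lines for 271 genes, 37 with a higher and 234 with a lower change in UCLA1. The germline genes RNF17 (difference of log2 fold changes 6.85 ± 0.72, adjusted p = 0.00865), TDRD12 (6.10, adjusted p = 0.0232) and TEX11 (5.49 ± 0.63) and the T-cell lymphoma gene TCL1B (4.03 ± 0.63) rose with the label in UCLA1 relative to UCLA4. The receptors KDR (-6.32 ± 0.57, adjusted p = 0.00802) and FLT1 (-5.65 ± 0.57) went down with it. So did the collagens COL4A2 (-6.02 ± 0.87), COL18A1 (-5.93 ± 0.83), COL4A1 (-5.79 ± 0.75) and COL6A3 (-5.57 ± 0.80), PODXL (-5.93 ± 0.72) and the WNT target SP5 (-6.27 ± 0.78). Of 15 germline genes 2 were called (7 adjusted over the list alone; camera adjusted p = 3.99e-08, adjusted p = 0.22 with an estimated correlation). WNT targets were lower in 3 of 11 cases (7 adjusted over the list alone; camera adjusted p = 8.06e-07, adjusted p = 0.22 with an estimated correlation). Of 10 genes of preimplantation genome activation 0 were called by edgeR (8 up adjusted over the list alone; camera adjusted p = 3.99e-08, adjusted p = 0.366 with an estimated correlation). The X shifts of the 2 lines differed by -0.013 (camera p = 0.813, p = 0.79 with an estimated correlation), a value whose sign changed with the filter, the summary and single libraries. Genes subject to X inactivation fell less in UCLA1 as a list, with a median of 0.34 (camera adjusted p = 0.0177, adjusted p = 0.398 with an estimated correlation). Of these 55 genes 1 was called, with the lower change in UCLA1. The 271 calls became 0 without either UCLA4 library labelled XIST-negative or with these summed, and 49 without the first clone 4 library. There were 116 and 136 without the second and the first clone 12 library, 92 without the first UCLA4 library labelled XIST-positive and 416 without the first clone 9 library. DESeq2 made 1168 and the term for second libraries 1066. Of these 27.7% and 37.1% were higher against 13.7%, with 32.6% and 6.88% without the first and the second UCLA4 library labelled XIST-positive and 4.08% without the first clone 4 library.

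Late-passage clone 4, labelled XIST-positive, was compared with the same clone labelled XIST-negative. Late cells held higher levels of RNF17 and PEG3 and lower levels of COL6A3, COL4A1 and X-linked genes as a class. RNF17 rose by 4.81 ± 0.58 (adjusted p = 0.0023; 66.8 against 2.37 ± 1.14 CPM; n = 1 and 2). PAX8-AS1 rose by 4.37 ± 0.48, PEG3 by 3.94 ± 0.46 (adjusted p = 0.00219; 39.8 CPM) and CYP2E1 by 3.93 ± 0.56. Rises were also called for SAP25 (3.49 ± 0.76), the X-linked PNMA5 (3.11 ± 0.76) and GTSF1 (3.04 ± 0.60). ACTC1 (-9.49 ± 1.54), the collagen COL6A3 (-9.10 ± 1.13), KDR (-7.01 ± 0.72), LEF1 (-5.80 ± 1.03), COL4A1 (-4.91 ± 0.87) and HMGA2 (-4.23 ± 0.37, adjusted p = 0.000862) fell. LUM was at least 5340-fold lower, with 0 counts in the late library. The late library stood beyond both earlier ones for each of these genes, and, as the lone library of its group, it was assumed to vary like the other groups. In all 1378 genes passed, 337 higher and 1041 lower. Of 12 fibroblast genes 3 fell (9 adjusted over the list alone; camera adjusted p = 0.000197, adjusted p = 0.529 with an estimated correlation). Of 15 germline genes 3 rose (6 adjusted over the list alone; camera adjusted p = 0.000197, adjusted p = 0.509 with an estimated correlation). Among 25 naive genes 1 rose (8 adjusted over the list alone; camera adjusted p = 0.000197, adjusted p = 0.509 with an estimated correlation), TFAP2C (1.54 ± 0.37).

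X-linked genes were lower in late clone 4, with 95 of 609 called lower (15.6%, against 5.74% of autosomal genes) and 4 higher. The X shift was -0.88, or 54.5% of the level relative to autosomal genes, and 80.3% of X-linked genes lay below the autosomal median (camera p = 4.47e-11, p = 0.000242 with an estimated correlation). HS6ST2 (-5.84 ± 0.84), FHL1 (-4.53 ± 0.81), LRCH2 (-4.24 ± 0.47), IDS (-3.52 ± 0.67) and ACSL4 (-2.33 ± 0.36) fell, and IDH3G rose (1.06 ± 0.25). The median of chromosome X lay at -0.84 against all genes, and autosomes ran from -0.27 for chromosome 5 to 0.43 for chromosome 19. At the preset correlation 3 autosomes were called as sets. The late library was deposited in another file format than early clone 4. The 8 libraries of the first format and the 6 of the second were parted by at least 4-fold in 125 genes. These genes were picked from the same libraries, which nearly fixed their calls in this contrast, and 125 were called here. Among them were the pseudoautosomal SLC25A6 (at least 5150-fold lower, 0 counts), CSNK1E (ratio 1680, 95% counting interval 464 to 13800), ANXA2P2 (-9.83), POU5F1P3, RPS26P11 and PGAM4 (-8.99), and, on the higher side, the pluripotency factor UTF1 (3.33 ± 0.70). Several of these have near-identical copies elsewhere in the genome. Without these genes 1142 calls were made and the X shift was -0.86. The count of 1378 was 423 without the first clone 4 library, 4467 with the term for second libraries, where 2043 were higher, and 2647 by DESeq2. Of calls without the first clone 4 library 6.15% were higher, against 24.5%.

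The reprimed sample was compared with primed cells to ask how far it had returned to the primed state. It held primed genes at levels not called different from those of primed cells (0 of 21 called, 0 adjusted over the list alone; camera adjusted p = 0.582), while members of the endoderm, primitive streak and imprinted lists were higher than in primed cells. PEG3 was 92.6 CPM in the reprimed sample against 1 count in primed cells (ratio 5120, 95% counting interval 918 to 202000). CDX1, a caudal homeobox gene, had 1 count in primed cells as well (ratio 269, 95% counting interval 47.5 to 10700), as had DSCR8 (ratio 286, 50.7 to 11400). C17orf51 (ratio 401, 137 to 1950) and the amino acid transporter SLC6A19 (ratio 202, 55.2 to 1670) had 3 and 2 counts. TEKT4P2 rose by 7.59 ± 0.51, the imprinted noncoding RNA H19 by 7.52 ± 1.15 (adjusted p = 0.00558; 1185 against 6.47 ± 3.04 CPM; n = 1 and 2) and HAND1 by 7.27 ± 0.69 (adjusted p = 0.00071). Of 12 hypoblast and endoderm genes 10 rose (12 adjusted over the list alone; camera adjusted p = 1.66e-09, adjusted p = 0.115 with an estimated correlation). They were led by the apolipoprotein APOA1 (6.28 ± 0.58, adjusted p = 0.000625; 325 against 4.19 ± 0.69 CPM), GATA4 (5.45 ± 0.68), HNF4A (5.21 ± 0.85) and FOXA2 (4.82 ± 0.84). Of 7 mesoderm and streak genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.000626, adjusted p = 0.115 with an estimated correlation), with GSC (4.66 ± 0.71), EOMES (3.22 ± 0.62) and MIXL1 (3.16 ± 0.66). WNT targets rose in 6 of 11 cases (9 adjusted over the list alone; camera adjusted p = 3.5e-07, adjusted p = 0.115 with an estimated correlation), with SP5 at 5.16 ± 0.67. Of 24 imprinted genes 9 rose (12 adjusted over the list alone; camera adjusted p = 2.54e-05, adjusted p = 0.115 with an estimated correlation), including DLK1 (3.53 ± 0.53) and NLRP2 (2.84 ± 0.28). Naive genes had not all returned to primed levels: 9 of 25 were higher (14 adjusted over the list alone; camera adjusted p = 8.63e-07, adjusted p = 0.12 with an estimated correlation). TRIM60 was at 7.84 against 0.09 ± 0.023 CPM (6.37 ± 0.33), DPPA3 at 352 against 6.04 ± 2.68 CPM (5.86 ± 0.70) and DNMT3L at 17.4 against 1.57 ± 0.079 CPM (3.47 ± 0.27). Of 18 MEK and ERK targets 4 rose (9 adjusted over the list alone; camera adjusted p = 6.27e-05, adjusted p = 0.261 with an estimated correlation), FOSL1 by 2.97 ± 0.50. The reprimed library stood beyond both primed ones for each gene named.

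XIST was not called different between the reprimed sample and primed cells (-0.86 ± 1.28, adjusted p = 0.728), and X-linked genes were higher than in primed cells. Of 609 tested 55 rose (9.03%, against 4.1% of autosomal genes) and 17 fell, and the X shift was 0.52, or 143% of the level relative to autosomal genes (camera p = 1.22e-05, p = 0.00212 with an estimated correlation). Autosomes spread widely here, with medians from -0.28 for chromosome 13 to 0.41 for chromosome 22 against all genes, and X lay at 0.51. SLITRK2 (6.90 ± 0.93), the B-cell kinase BTK (3.92 ± 0.57), the dystrophin gene DMD (3.81 ± 0.35, adjusted p = 0.00057; 254 against 18.1 ± 1.17 CPM), RENBP (3.45 ± 0.33) and PRICKLE3 (3.05 ± 0.59) rose. MAGEB2 had 2 counts in primed cells (ratio 17.7, 95% counting interval 4.29 to 156). GDPD2 (-2.57 ± 0.62), TDGF1P3 (-2.56 ± 0.49), NLGN4X (-1.96 ± 0.32, adjusted p = 0.00719) and BEX2 (-1.85 ± 0.46) fell. Of 55 genes subject to X inactivation 5 rose (10 adjusted over the list alone; camera adjusted p = 0.000173, adjusted p = 0.115 with an estimated correlation). Of 28 escape genes 0 were called by edgeR (0 adjusted over the list alone; camera adjusted p = 0.582). The escape minus subject mean was -0.60 (permutation p = 0.0012 across genes, which are not independent replicates; Benjamini-Hochberg p = 0.0048 over 8 contrasts). In all 1008 genes passed, 705 higher and 303 lower, the lone reprimed library being assumed to vary like the other groups. Of the 125 genes that part the file formats, 124 were among the calls, which their choice from these same libraries nearly fixed. They made up 18 of the 20 deepest falls. At 0 counts were SLC25A6 (at least 5310-fold), CSNK1E (at least 1070-fold) and RPS26P11 (at least 1050-fold lower). AHCTF1P1, PGAM4, RPL23P8 and POU5F1P3 belong to the same set. Without them 786 calls were made, 81.0% of them higher against 69.9%, and the X shift was 0.55. The count of 1008 was 466 without the second primed library, 165 from the compared groups alone, 2383 with the term for second libraries and 1796 by DESeq2. The share of higher calls was 58.4% without the second primed library, and from the compared groups alone most calls were lower (41.2% higher).

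Set against naive cells, the reprimed sample held most naive genes at lower levels and most primed genes at higher levels. Of 21 primed genes 19 rose (20 adjusted over the list alone; camera adjusted p = 7.92e-14, adjusted p = 0.0508 with an estimated correlation). They included PTPRZ1 (7.89 ± 0.36, adjusted p = 6.56e-06; 209 against 1.18 ± 0.98 CPM), THY1 (7.88 ± 0.36) and DNMT3B (2.74 ± 0.28; 2050 against 309 ± 47.5 CPM). Of 25 naive genes 18 fell (20 adjusted over the list alone; camera adjusted p = 6.56e-16, adjusted p = 0.0508 with an estimated correlation). DPPA5 (-8.99 ± 0.71), KHDC3L (-8.89 ± 0.65), OLAH (-7.48 ± 0.58) and DNMT3L (-6.08 ± 0.36) fell with them. CNR2, at 0 counts in the reprimed sample, was at least 263-fold lower, and ATP6V1B1 had 1 count (ratio 1110, 95% counting interval 200 to 44000). USP44 (6.18 ± 0.38), VRTN (5.89 ± 0.29), PDZD4 (5.86 ± 0.49), the WNT receptor FZD7 (5.82 ± 0.94), SPP1 (5.75 ± 0.43), IGFBP4 (5.75 ± 0.27), TP53I11 (5.25 ± 0.55) and ID3 (5.18 ± 0.90) were the largest rises among genes with a mean log2 CPM of at least 2. Of 18 MEK and ERK targets 17 rose (18 adjusted over the list alone; camera adjusted p = 4.46e-11, adjusted p = 0.0937 with an estimated correlation), DUSP6 by 7.19 ± 0.53 and ETV5 by 5.95 ± 0.40. Endoderm genes rose in 8 of 12 cases (9 adjusted over the list alone; camera adjusted p = 3.38e-05, adjusted p = 0.256 with an estimated correlation), APOA1 by 10.13 ± 0.43 and SOX17 by 7.86 ± 0.63. Streak genes rose in 6 of 7 cases (7 adjusted over the list alone; camera adjusted p = 5.01e-05, adjusted p = 0.0933 with an estimated correlation), EOMES by 6.43 ± 0.45. Of 10 genes of preimplantation genome activation 8 fell (9 adjusted over the list alone; camera adjusted p = 2.91e-06, adjusted p = 0.328 with an estimated correlation). XIST fell by 9.04 (-9.04 ± 1.59, adjusted p = 0.00316), and 193 X-linked genes rose (31.7%, against 15.3% of autosomal genes) while 37 fell, an X shift of 0.56 (camera p = 5.06e-05, p = 0.0031 with an estimated correlation). TMEM47 (4.93 ± 0.22), ARSE (4.62 ± 0.68), ARHGAP4 (4.12 ± 0.44) and BEX1 (4.02 ± 0.59) were among these rises. For every gene named here the reprimed library lay beyond all 6 naive ones. In all 4162 genes passed, 2617 higher and 1545 lower. There were 4003 without the 125 genes that part the file formats, all of which were called, as their choice nearly fixed. The count was 2123 from the compared groups alone and 6695 with the term for second libraries.

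Clones 12 and 9, both labelled XIST-positive, gave the size of a difference between clones that share a label. By edgeR no gene was called between them: 0 of 16548 passed its test and 472 had an unadjusted p under 0.05, while DESeq2 called 17. XIST gave 0.50 ± 0.80 (adjusted p = 1) and the X shift was -0.024 (limma camera p = 0.266, p = 0.239 with an estimated correlation), with a range of -0.12 to 0.067 when single libraries of the pair were left out. Primed genes were lower in clone 12 as a list (median -0.98; 0 of 21 called, 3 down adjusted over the list alone; camera adjusted p = 2.79e-05, adjusted p = 0.363 with an estimated correlation). Genes of preimplantation genome activation were higher as a list (median 0.72, 0 of 10 called, camera adjusted p = 0.000221, adjusted p = 0.685 with an estimated correlation). The genes of 9 autosomes differed as sets at the preset correlation, though the clones share a label. With an estimated correlation, chromosomes 3, 7, 10 and 21 passed, chromosome 7 at -0.076 (camera adjusted p = 0.0488). Chromosome 10 lay 0.28 (log2) above all genes in clone 12 relative to clone 9 (adjusted p = 2.08e-10, adjusted p = 0.00267 with an estimated correlation; limma camera). Chromosome 21 lay 0.285 above (adjusted p = 7.97e-07, adjusted p = 0.0174 with an estimated correlation), while chromosome 3 was at -0.12 (adjusted p = 0.00267 with an estimated correlation). The level of chromosome 10 was 0.10 and 0.11 in the libraries of clone 12 and -0.11 and -0.085 in those of clone 9, the same sign in both libraries of each clone.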

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

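In this part the tests of XIST state, of other differentiated cells, of the median of long transcripts and of the genes that part the formats were chosen after the results were seen, and the summed UCLA4 libraries and the removal of GC and length trends were added after the data were seen.

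The XIST label contrast differed between the lines, by a test of the difference itself, for 271 genes. Among the genes named for a label contrast these were COL4A2 (-6.022), COL18A1 (-5.928), COL4A1 (-5.786), NPNT (-5.727), FLT1 (-5.647), LMCD1 (-5.563), HS6ST2 (-4.071), IL13RA1 (-3.807) and IDS (-3.073), with the lower change in UCLA1, and PAX8-AS1 (3.717), TEX11 (5.494) and RNF17 (6.852), with the higher. No call was left (0 by edgeR, 1640 genes with an unadjusted p under 0.05, 1168 by DESeq2 with all libraries) when the UCLA4 libraries labelled XIST-negative were summed.

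Genes listed in one file format alone held signal that no comparison used: 192 of 551 gene names in the first format and 323 of 1574 in the second had more than 3 counts in each library of that format.

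X-linked genes were lower in UCLA1 clones 9 and 12 than in clone 4 labelled XIST-negative, and stromal cells in clone 4 were argued against as the cause: the fibroblast list was 2.66-fold higher in its first library than in its second, yet their relative X levels differed by 0.00031, under the bound of 0.2 set for that cause. Mesodermal cells cannot be told apart from the clone, because the mesoderm list differed between the same libraries by -0.595 (log2), too little for a test. The trophoblast list lay at 1.64 in the first and 0.328 in the second library (log2), with relative X levels of 0.3145 and 0.3142. These values argue against trophoblast cells as the cause. Differentiated cells of other kinds cannot be told apart from the clone. Trends with GC content and transcript length were argued against as the whole cause, since the X shift was -0.606 after their removal. XIST state, clone and the number of X chromosomes, which was not measured, stay open: the X shift of -0.636 for the same labels in UCLA4 was known when that test was set. Late clone 4, labelled XIST-positive, held a relative X level of -0.276 against 0.314 for clone 4 labelled XIST-negative. That speaks against a lasting property of that clone, but late clone 4 is a single library of another passage and file format. Its fibroblast list also lay at -1.75 (log2), against 3.75 and 2.34 in the libraries labelled XIST-negative. The content of differentiated cells may thus have changed together with the label.

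XIST was lower in the second than in the first library of clone 9 by -2.83 (log2). Loss of long transcripts from the second library stays open: the change lay at percentile 4.02 of 473 genes with transcripts of at least 10000 bases, above the bound of 2.5, but their median change was -0.193, against -0.0365 for all genes. A culture with less XIST and a higher X level stays open as well, since the change in relative X level between the libraries was 0.0811 higher in clone 9 than in clone 12, which lay under the bound of 0.1 set against this by less than the pooled SD between replicates of 0.0361. No other biological explanation was tested.

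X-linked genes were higher in the reprimed library than in primed cells. The median of chromosome X lay at 0.51 against all genes, not far above the highest autosome (0.41, chromosome 22). Trends with GC content and transcript length were argued against, as the X shift was 0.66 after their removal. Leaving out the genes that part the file formats (X shift 0.554) was no test of them, since all 6 X-linked ones were higher in the first format and their removal could only raise the X-linked median. An effect of format cannot be told apart from the groups: the relative X level of libraries labelled XIST-positive was -0.126 in the second format minus the first, which met the bound of 0.1 set against it, but that bound was wrong, because line and passage differ between the formats and no group is in both. Reprimed cells are a single library, and whether a second X chromosome was active in them was not measured.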

How the results depend on the processing

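Tests chosen after the data were seen were the class term for second libraries, the naive mean without clone 4, clone 4 labelled XIST-negative alone against primed cells, second libraries left out, UCLA4 negatives summed, GC content and length, genes with a mean log2 CPM of at least 4, genes that part the formats left out, and escape minus subject genes.

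The X shift kept its sign and its side of the threshold under all alternatives run in the UCLA1 label contrast (-0.653 to -0.453), UCLA4 (-0.668 to -0.545), late against earlier clone 4 (-0.977 to -0.669), reprimed against primed (0.345 to 0.671) and reprimed against naive (0.426 to 0.667). For means in place of medians the camera test stayed the main one, so only the sign could change. The count of naive against primed calls stayed within 1.5 times of 6278 (4369 to 8904). Of named genes, lists and chromosomes under each alternative, 5397 results kept direction and side, 579 lost the call, 8 gained one and 0 reversed. Part of this was fixed in advance. Most named genes were picked from these data as called, many also with all libraries of one side above the other. They could therefore hardly reverse. Lists were varied only in the form of the set test, with a preset or an estimated correlation, and could not reverse. Chromosomes were varied only in the summary and could not lose a call. Of the results that answer a comparison, 283 were the same by these measures, 43 moved, 12 passed the threshold anew and 21 changed sign. Where a value below moved, the cause was not tested, except that fewer libraries leave fewer degrees of freedom. Depth limits genes of few counts. The self-test recovered few 2-fold changes, but with far fewer genes changed than were called between naive and primed cells. The replicate block was fitted without late clone 4 and the reprimed sample, so it was not run for their contrasts.

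Counts of calls moved by over 1.5 times as follows. The UCLA1 label contrast (2566) gave 1186 from the compared groups alone, 4556 with the class term and 662 to 2878 with each library left out. UCLA4 (4) gave 8 with no filter, 141 from the compared groups alone, 112 with the class term, 0 by edgeR with the negatives summed (456 genes with an unadjusted p under 0.05), 162 by DESeq2 and 0 to 3 with each library left out. Late against earlier clone 4 (1378) gave 4467 with the class term, 2647 by DESeq2 and 423 to 1133 with each library left out. Reprimed against primed (1008) gave 165 from the compared groups alone, 2383 with the class term, 1796 by DESeq2 and 466 to 1429 with each library left out. Reprimed against naive (4162) gave 2123 from the compared groups alone and 6695 with the class term. Clone 12 against clone 9 (0 by edgeR, 472 with an unadjusted p under 0.05) gave 17 by DESeq2 and 0 to 1 with each library left out. The difference between lines (271) gave 445 with the replicate block, 1066 with the class term, 0 by edgeR with the negatives summed (1640 with an unadjusted p under 0.05), 1168 by DESeq2 and 0 to 416 with each library left out. The replicate block gave 3148 calls for the UCLA1 label contrast, 4 for UCLA4, 6705 for naive against primed and 0 by edgeR for clone 12 against clone 9. The lists past the set test with an estimated correlation were 0 of 9 for naive against primed, 0 of 10 for the UCLA1 label contrast, 1 of 10 for UCLA4, 0 of 7 for late clone 4, 0 of 10 and 0 of 8 for reprimed against primed and naive, 0 of 2 for clone 12 against clone 9 and 0 of 11 for the difference between lines.

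X shifts that were not called changed as follows. Naive against primed (-0.048) was 0.1034 with no filter and 0.1896 at a mean log2 CPM of at least 4. Clone 12 against clone 9 (-0.024) was 0 with no filter, 0.01395 at a mean log2 CPM of at least 4 and -0.1163 to 0.06715 with each library left out. The difference between lines (-0.013) was 0.01753 with no filter, 0.02305 with the replicate block, 0.0579 by the mean and -0.06758 to 0.01577 with each library left out, and the median of chromosome X was 0.0557 by the mean. Clones 9 and 12 against primed cells (-0.29) gave -0.2808 at 2 CPM, 0.00826 at a mean log2 CPM of at least 4 and -0.3159 to -0.2424 with each library left out. Clone 4 against primed cells (0.38) passed the threshold with DESeq2 size factors (0.3771), no filter (0.4626), 2 CPM (0.4203), the replicate block (0.3911), the class term (0.4577), no escape genes (0.394), a mean log2 CPM of at least 4 (0.5575) and GC and length trends removed (0.3837). With libraries left out the shift was 0.3232 to 0.4417, past the threshold for some of them but not without the first primed library.

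The relative X level of naive against primed libraries (0.005) was -0.01351 with a pseudocount of 0.25, -0.02108 at 2 CPM, -0.1539 by the mean, -0.03494 with late clone 4 and -0.05716 to 0.04354 with each library left out. That of libraries labelled XIST-positive against XIST-negative (-0.4614) kept its sign and was -0.1668 with no filter, -0.6039 at 2 CPM, -0.6052 with a pseudocount of 0.25, -0.4703 by the mean and -0.4742 to -0.449 with each library left out. Escape minus subject genes in the UCLA1 label contrast (0.017) ranged from -0.0275 to 0.0888 with each library left out.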

Other observations

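The comparisons in this part of escape with subject genes, and of single chromosomes between clones, were chosen after the results were seen.

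Genes known to escape X inactivation and genes subject to it differed between naive and primed UCLA1 cells, with a mean of escape minus subject genes of -0.56 (permutation p = 0.01 across genes, Benjamini-Hochberg p = 0.027 over 8 contrasts), with subject genes such as BTK and LAMP2 higher in naive cells. The difference was 0.26 in late against earlier clone 4 (permutation p = 0.16, Benjamini-Hochberg p = 0.21) and -0.044 in reprimed against naive cells (permutation p = 0.82, Benjamini-Hochberg p = 0.92). It was 0.14 in clone 12 against clone 9 (permutation p = 0.015, Benjamini-Hochberg p = 0.03) and -0.33 in the difference between lines (permutation p = 0.099, Benjamini-Hochberg p = 0.16). Genes are not independent replicates in any of these.

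Chromosome 10, which differed between clones 12 and 9, lay lower in UCLA4 labelled XIST-positive by a call (adjusted p = 0.0247) that was lost (adjusted p = 0.0939 with an estimated correlation). Its level per library was -0.134 and -0.176 in UCLA4 labelled XIST-positive and 0.0022 and -0.011 in UCLA4 labelled XIST-negative. Chromosome 21 was at -0.195 and -0.136 in clone 9, -0.038 and 0.0038 in clone 12, and -0.0653 to 0.078 in the other libraries.

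The genome activation gene ZSCAN4 held 9.87 and 3.1 CPM in clone 12, 6.07 and 1.34 CPM in clone 9, 2.65 and 2.51 CPM in clone 4 labelled XIST-negative, 4.57 and 4.68 CPM in UCLA4 labelled XIST-negative and 1.54 and 0.92 CPM in UCLA4 labelled XIST-positive. The log2 fold change in UCLA4 was -1.91 ± 0.78 (adjusted p = 0.707). VGLL1 (2.53 ± 1.27, adjusted p = 0.793) and GCM1 (1.60 ± 0.96, adjusted p = 0.861), both trophoblast genes, were not called there either.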
